A study of Mus musculus with 12 samples.

How the data were processed

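RNA of G1E-ER-GATA-1 cells was sequenced in 12 libraries, 3 per group: untreated WT cells, WT cells with estradiol, mutant cells with estradiol, and mutant cells with estradiol and 5-ALA. Total RNA was purified with TRIzol and made into libraries with a TruSeq kit, according to the labels. The submitters' processing notes name CASAVA 1.8.2, RSEM 1.2.20, Bowtie 1.1.1 and the genome build mm10. The read length, the annotation release and whether strand was used in counting are not given in the sources used here.

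Each library has a table of 25097 genes. The deposited tables give, per the file headers, the RSEM expected count of each gene, that is, the reads assigned to its transcripts with shared reads divided by likelihood. The authors' tables also give TPM and FPKM, both scaled for transcript length and library size, and the abundance-weighted length and effective length of each gene. Expected counts were used for all tests and TPM for 1 alternative. The length column served 1 check and the matching of random lists to the ribosomal protein genes. FPKM was not used here. The effective length was 49 bases below the length. Expected counts split reads among paralogs by a model, so values of the near-identical globin genes depend on each other. Genes with overlapping exons can share reads too: those named below are Alas2 with Apex2, Tmem184a with Mafk, Slc48a1 with Hdac7, Sptb with Plekhg3, Ppp1r15a with Tulp2, Rpl12 with Lrsam1, Rps18 with Vps52, Fam162a with Wdr5b, Cebpb with Tmem189, mt-Atp6 with mt-Atp8 and mt-Co3, and Cox15 with Entpd7 and Cutc. Gene symbols and positions came from GENCODE M21, which matched 24746 of the identifiers. List members whose symbols are not in the tables were Ahsp, Hbb-b1, Hbb-b2, Hbb-bh0, Ighm and Trac.

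Expected counts were rounded and filtered with filterByExpr by group, which kept 12115 genes. They were scaled by TMM and fitted with edgeR 4.0.16 in R 4.3.3 as 4 group means over all 12 libraries, with robust estimation. Groups were compared with the edgeR quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method over the 12115 genes. A gene is called, or said to have risen or fallen, at an adjusted p below 0.05. Where an SE is printed, it is the absolute log2 fold change over the square root of its F statistic. It is an approximation and not a standard error given by the fit. Groups of 3 libraries share 1 estimate of the spread. The common biological coefficient of variation was 0.0334, a spread between libraries that may be mostly technical, so that small differences pass the test. The design, gene lists, rule for named genes and alternatives were fixed before the data were examined, except where a later choice is stated.

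The named genes were Alas2, Gata1 and Gata2, and in each comparison the 6 largest rises and 6 largest falls. Those had to be called, to have a mean of at least 10 CPM over both groups, and to have groups that did not overlap. For the reversal by 5-ALA, 6 genes per direction were taken by the smaller of the absolute log2 fold changes. From each list came up to 4 called members with the largest change and at least 1 CPM, or the most abundant member where none was called. Members named because they went against most of their list, genes repeated across comparisons, the adult globins, Blvra and Bach1 were chosen after their values were seen. Values of some list members are not reported here.

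The 24 gene lists covered heme synthesis, iron and heme transport, heme degradation and antioxidant genes, globins, red cell membrane, erythroid transcription factors, and stem and progenitor genes. They further covered autophagy, zinc, ATF4 stress response, heat shock, ribosomal proteins, S phase and mitosis, cell cycle inhibitors and p53 response, respiratory complexes and circadian regulators. The rest were cholesterol, proteasome, mitochondrial mRNAs, and markers of megakaryocytes, mast cells, granulocytes, lymphocytes and fibroblasts. Each was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison, and again with the correlation estimated from the data. Some lists share members, for example Slc7a11, Slc48a1 and Slc40a1.

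Overlaps of calls were set beside the number that independence gives and beside 20 simulations of unchanged groups with the real library sizes and dispersions. The share of a difference undone by 5-ALA is the log2 change with 5-ALA over the mutant-WT log2 difference, with the sign turned. Ratios of named genes with 20 or fewer counts over a group were computed from the summed counts with exact Clopper-Pearson 95% intervals, which cover counting error only. For neighbouring genes, medians were taken over 25 genes in genome order and compared with 1000 shuffles of the gene order. That check and its segment borders were chosen after the values were seen.

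The fit was tested on simulated data with 200 changed genes. It recovered 73.1% of those changed 1.25-fold, 94% of those changed 1.5-fold and 97% of those changed 2-fold, and 9 of its 185 calls (4.86%) were unchanged genes. In an unchanged comparison of the same simulation edgeR made 0 calls. The simulated counts came from the fitted model and few genes were changed, while far more genes were called in the data. These rates therefore need not hold for the comparisons below. At these depths pairs of libraries of a group differed by more than counting error, with a chi-square per degree of freedom from 1.8 to 16.69.

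The alternatives were DESeq2 size factors, globin genes left out before scaling, no filter, a stricter filter of at least 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-trend on log2(TPM + 1), fits on the compared groups alone, the replicate number as a block, and each library left out in turn. For the lists, the fry test was run as well. An alternative chosen after the data were seen left out 3 libraries together.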

Results

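Transcript levels were measured by RNA sequencing in 12 libraries of G1E-ER-GATA-1 cells. These are mouse erythroid precursor cells that lack the endogenous transcription factor GATA-1 and carry GATA-1 fused to the ligand-binding domain of the estrogen receptor, so that beta-estradiol switches the fusion protein on and starts erythroid maturation. The libraries formed 4 groups of 3. Wild-type (WT) cells were untreated or received 1 µM beta-estradiol for 48 h. Mutant cells, in which cis-elements of Alas2 are altered, received estradiol alone or estradiol with 1 mM 5-aminolevulinic acid (5-ALA). Alas2 encodes the erythroid enzyme that makes 5-ALA, the first precursor of heme, and added 5-ALA enters the pathway after that step. The labels call the cells double mutants without naming the elements, and their place in Alas2 is given here from general knowledge of the study.

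The libraries held between 20309085 and 43548387 expected counts, and 12115 of 25097 genes had enough counts to be tested. Within a group, the libraries correlated across genes with Pearson's r between 0.99232 and 0.99488. The first principal component, with 84.8% of the variance, parted untreated from estradiol-treated cells. The second, with 8.53%, parted WT from mutant cells among the treated ones. The third, with 1.79%, parted mutant cells with 5-ALA from those without it.

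**Figure D1:**
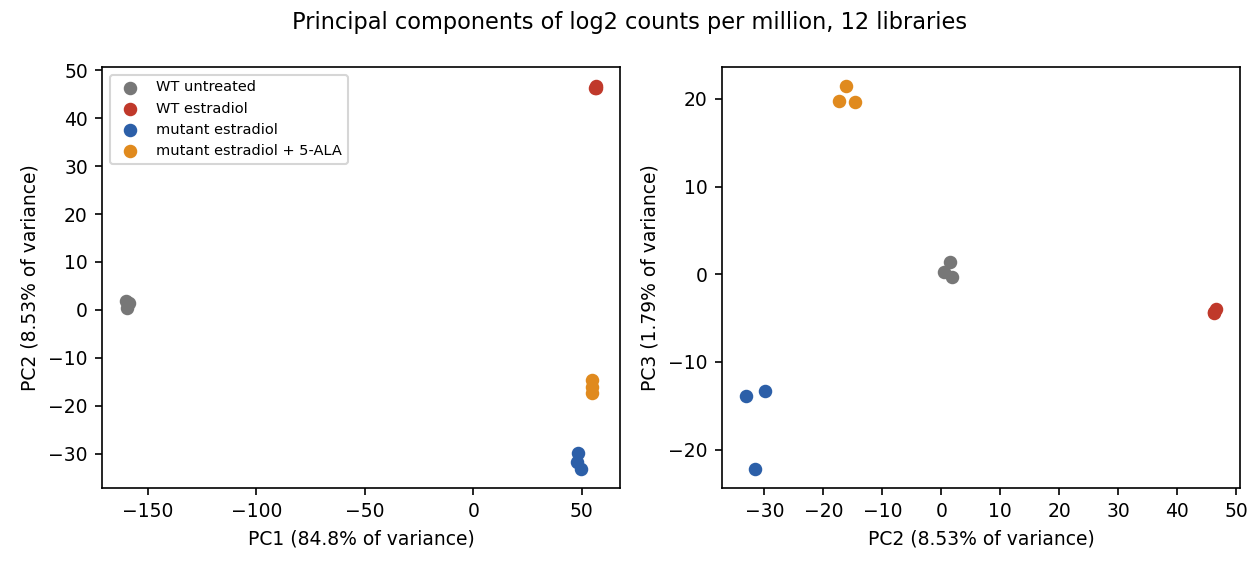
Principal components of log2 CPM in the 12 libraries, 1 point per library, with the axes giving each component's score and its percent of the variance. The 3 libraries of a group lie together, and each of the 3 components shown separates a different pair of conditions.

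The targeted gene followed the labels in every library. Alas2 (ENSMUSG00000025270, mm10 chromosome X, 150547375 to 150570638, plus strand, protein-coding) stood at 5.12 ± 0.767 CPM in untreated WT cells (counts per 1000000 after scaling, mean ± SD, n = 3, as for all CPM values below). It stood at 4293 ± 15.1 CPM in WT cells with estradiol, 7.64 ± 2.20 CPM in mutant cells with estradiol and 12.3 ± 0.237 CPM in mutant cells with estradiol and 5-ALA. Exons of Apex2 overlap those of Alas2 in the annotation, so some reads may belong to either gene. Gata1 (chromosome X, 7959260 to 7978071, minus strand) had 444 ± 3.87, 868 ± 11.7, 722 ± 11.3 and 715 ± 24.5 CPM in the same order. Gata2 (chromosome 6, 88193891 to 88207032, plus strand), a GATA factor of progenitor cells, had 483 ± 13.6, 59.8 ± 0.730, 28.0 ± 0.546 and 27.7 ± 1.81 CPM. Because the cells lack endogenous GATA-1 and carry it as a fusion, reads counted at Gata1 may come largely from the fusion. The counts do not tell it from transcripts of the native locus. The same limit holds where Gata1 is counted among the erythroid transcription factors. Gata1 was lower in mutant than in WT cells with estradiol, with no overlap between libraries. Whether a lower level of the fusion contributes to differences between these cells was not tested.

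**Figure D2:**
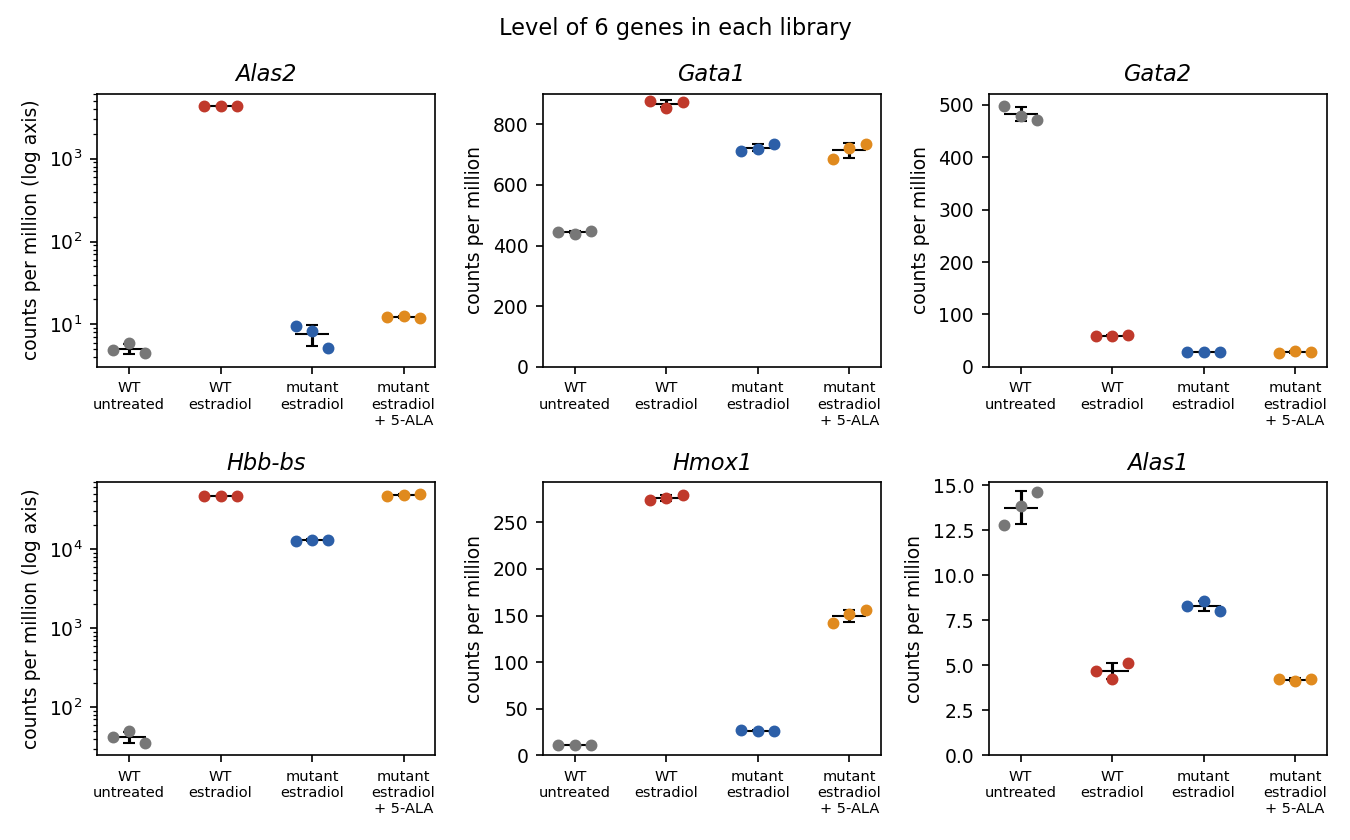
Level of 6 genes in CPM (log axis for Alas2 and Hbb-bs), with 1 point per library and bars for the mean ± SD of the 3 libraries of each group. Alas2 is high in WT cells with estradiol and stays at 5.2 to 12.5 CPM in every mutant library, while Hbb-bs, Hmox1 and Alas1 differ between mutant cells with and without 5-ALA.

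The first comparison, WT cells with estradiol against untreated WT cells, asks which genes respond when GATA-1 activity is restored. Most globin, red cell membrane and heme synthesis genes rose, and genes of DNA replication and mitosis fell, as lists by camera with its preset correlation but not with an estimated one (adjusted p = 0.219, 0.0819, 0.0819 and 0.23). The adult beta-globin gene Hbb-bs rose from 42.3 ± 6.93 to 46811 ± 381 CPM (log2 fold change 10.12, SE 0.124, adjusted p = 6.45e-13). All 9 tested members of the globin list rose, and globins took 6.59 ± 0.0315% of all counts with estradiol against 0.0272 ± 0.00162% without. Of 12115 genes tested, 5243 were higher and 5621 lower with estradiol in the edgeR quasi-likelihood test, 3206 and 3672 of them by 2-fold or more.

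The genes with the largest rises were the embryonic globins Hbb-y (log2 10.71, SE 0.0551) and Hbb-bh1, then Hbb-bs, Tmem184a, Hba-x and Alas2 (log2 9.74). Hbb-bh1 had 18 counts over the untreated libraries, for a ratio of 1541 with a 95% interval of 975 to 2600. The embryonic alpha-like globin Hba-x had 8, for a ratio of 927.8 with an interval of 471 to 2150. The membrane protein gene Tmem184a rose to 300.2 ± 3.42 CPM, and its exons overlap those of the transcription factor gene Mafk, which also rose (log2 4.71). The largest falls were those of Car1, Erv3, Tespa1, Melk, Rgs18 and Fam107b. Car1, which encodes carbonic anhydrase 1, went from 25.4 ± 1.01 to 0.0677 ± 0.0675 CPM, a 420.6-fold fall with an interval of 180 to 1300 from 5 counts over the estradiol libraries. Melk, a kinase gene of dividing cells, fell by 7.11 on the log2 scale, and Erv3, an endogenous retroviral gene, by 7.91.

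Red cell genes formed several groups that moved together. Of 21 tested genes for the red cell membrane, blood groups and glucose or gas handling, 18 rose and 2 fell, Car1 and Rhag (camera adjusted p = 1.12e-05, and adjusted p = 0.0819 with an estimated correlation). Slc4a1, the band 3 anion exchanger, rose from 7.10 ± 0.848 to 2821 ± 11.2 CPM and Sptb, which encodes beta-spectrin, from 73.6 ± 3.50 to 4714 ± 41.1 CPM. Of the 9 heme synthesis enzymes 8 rose, and only Alas1, the form of ALA synthase not restricted to the erythroid lineage, fell (log2 -1.56). The list had a camera adjusted p = 0.00205, and adjusted p = 0.0819 with an estimated correlation. Of the 27 genes for iron and heme transport and iron-sulfur clusters 19 rose and 6 fell (adjusted p = 0.00104, and adjusted p = 0.0819 with an estimated correlation). Of the 21 heme degradation and BACH1/NRF2-responsive antioxidant genes 15 rose and 5 fell, namely Blvra, Nqo1, Me1, Gsr and Gsta4 (adjusted p = 0.00205, and adjusted p = 0.0819 with an estimated correlation). Among these, the heme oxygenase gene Hmox1 rose from 11.1 ± 0.245 to 276 ± 3.08 CPM, and Ftl1, the ferritin light chain, had a log2 fold change of 4.45. The globin list had a camera adjusted p of 2.19e-05, and an adjusted p = 0.219 with an estimated correlation.

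Among 20 erythroid transcription factors and cofactors 16 rose and 4 fell (adjusted p = 0.00061, and adjusted p = 0.275 with an estimated correlation). Bach1, a heme-binding repressor, rose by a log2 fold change of 5.05, while E2f2, a regulator of the cell cycle, had -4.60, and Bcl11a, a repressor of globin genes, had -4.02. Sox6 and Nfe2l1 also fell. Of 15 stem and progenitor genes 10 fell and 4 rose, namely Hhex, Cd34, Meis1 and Runx1. As a list they missed the threshold, with an adjusted p = 0.0564 by camera. Kit, the receptor for stem cell factor, fell from 534 ± 3.50 to 17.7 ± 0.539 CPM, Myb had a log2 fold change of -6.74 and Gata2 of -3.01. Autophagy, mitophagy and enucleation genes rose in 17 of 21 cases and fell in 3, Atg4a, Atg5 and Atg7 (adjusted p = 8.22e-06, and adjusted p = 0.23 with an estimated correlation). They included Pink1, a kinase that marks mitochondria for removal (log2 4.76), and Gabarap, a component of autophagosomes (4.19).

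All 32 genes of S phase and mitosis fell, with a median log2 fold change of -4.10 (adjusted p = 1.05e-12, and adjusted p = 0.23 with an estimated correlation). The mitotic kinase genes Bub1b, Aurkb and Cdk1 had log2 fold changes of -6.87, -6.80 and -6.24. All 18 cell cycle inhibitors and p53-responsive genes rose (adjusted p = 3.52e-08, and adjusted p = 0.0819 with an estimated correlation), led by the antiproliferative gene Btg2, from 11.7 ± 0.634 to 2804 ± 15.2 CPM. Cytosolic ribosomal protein genes fell in 47 of 49 cases, with a median log2 fold change of -1.27. Rpl28 rose and Rpl19 did not pass the test (list adjusted p = 2.14e-10, and adjusted p = 0.346 with an estimated correlation). Proteasome subunits fell in 26 of 31 cases and rose in 5, Psmc2, Psmd4, Psmd8, Psmd11 and Psmd13 (adjusted p = 3.05e-05, and adjusted p = 0.346 with an estimated correlation). Respiratory complex genes fell in 20 of 27 cases and rose in 3, Sdhd, Uqcrh and Cox6a1 (adjusted p = 0.00267, and adjusted p = 0.439 with an estimated correlation). Of 13 mitochondrially encoded mRNAs 12 fell, and mt-Co1 rose (adjusted p = 0.0024, and adjusted p = 0.457 with an estimated correlation).

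In the other lists members went both ways, and camera made no call. Zinc transporters and metallothioneins rose in 8 and fell in 12 of 20 cases (adjusted p = 0.988). The zinc exporter gene Slc30a1 had a log2 fold change of 4.96 and Slc30a2 of -4.96. The ATF4 stress response list had 10 rises and 11 falls among 23 genes (adjusted p = 0.751). In it Pck2, mitochondrial phosphoenolpyruvate carboxykinase, had a log2 fold change of -5.04 and Ppp1r15a, a phosphatase subunit, of 5.02. Heat shock and immediate early genes rose in 6 and fell in 7 of 15 cases (0.986), circadian and heme-binding regulators in 6 and 6 of 12 (0.55), and cholesterol genes in 10 and 7 of 20 (0.365). Markers of other blood and stromal cells were mixed too: megakaryocyte genes rose in 5 and fell in 5 of 10 cases (0.986), mast cell and basophil genes in 2 and 6 of 8 (0.224), and granulocyte and macrophage genes in 2 and 5 of 7 (0.585). Lymphocyte genes rose in 3 cases and fell in 1 of 5 (0.986), and fibroblast and stromal genes rose in 1 and fell in 3 of 4 (0.24). The sign of the median, the mean and the test differed for the zinc, ATF4, heat shock, megakaryocyte and lymphocyte lists. Adjusted over the list alone, the counts were the same for all 24 lists, and with an estimated correlation camera called none of them. In limma-trend on log2(TPM + 1) the median over all genes shifted to -0.23, and 1818 genes were higher by 2-fold or more.

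**Figure D3:**
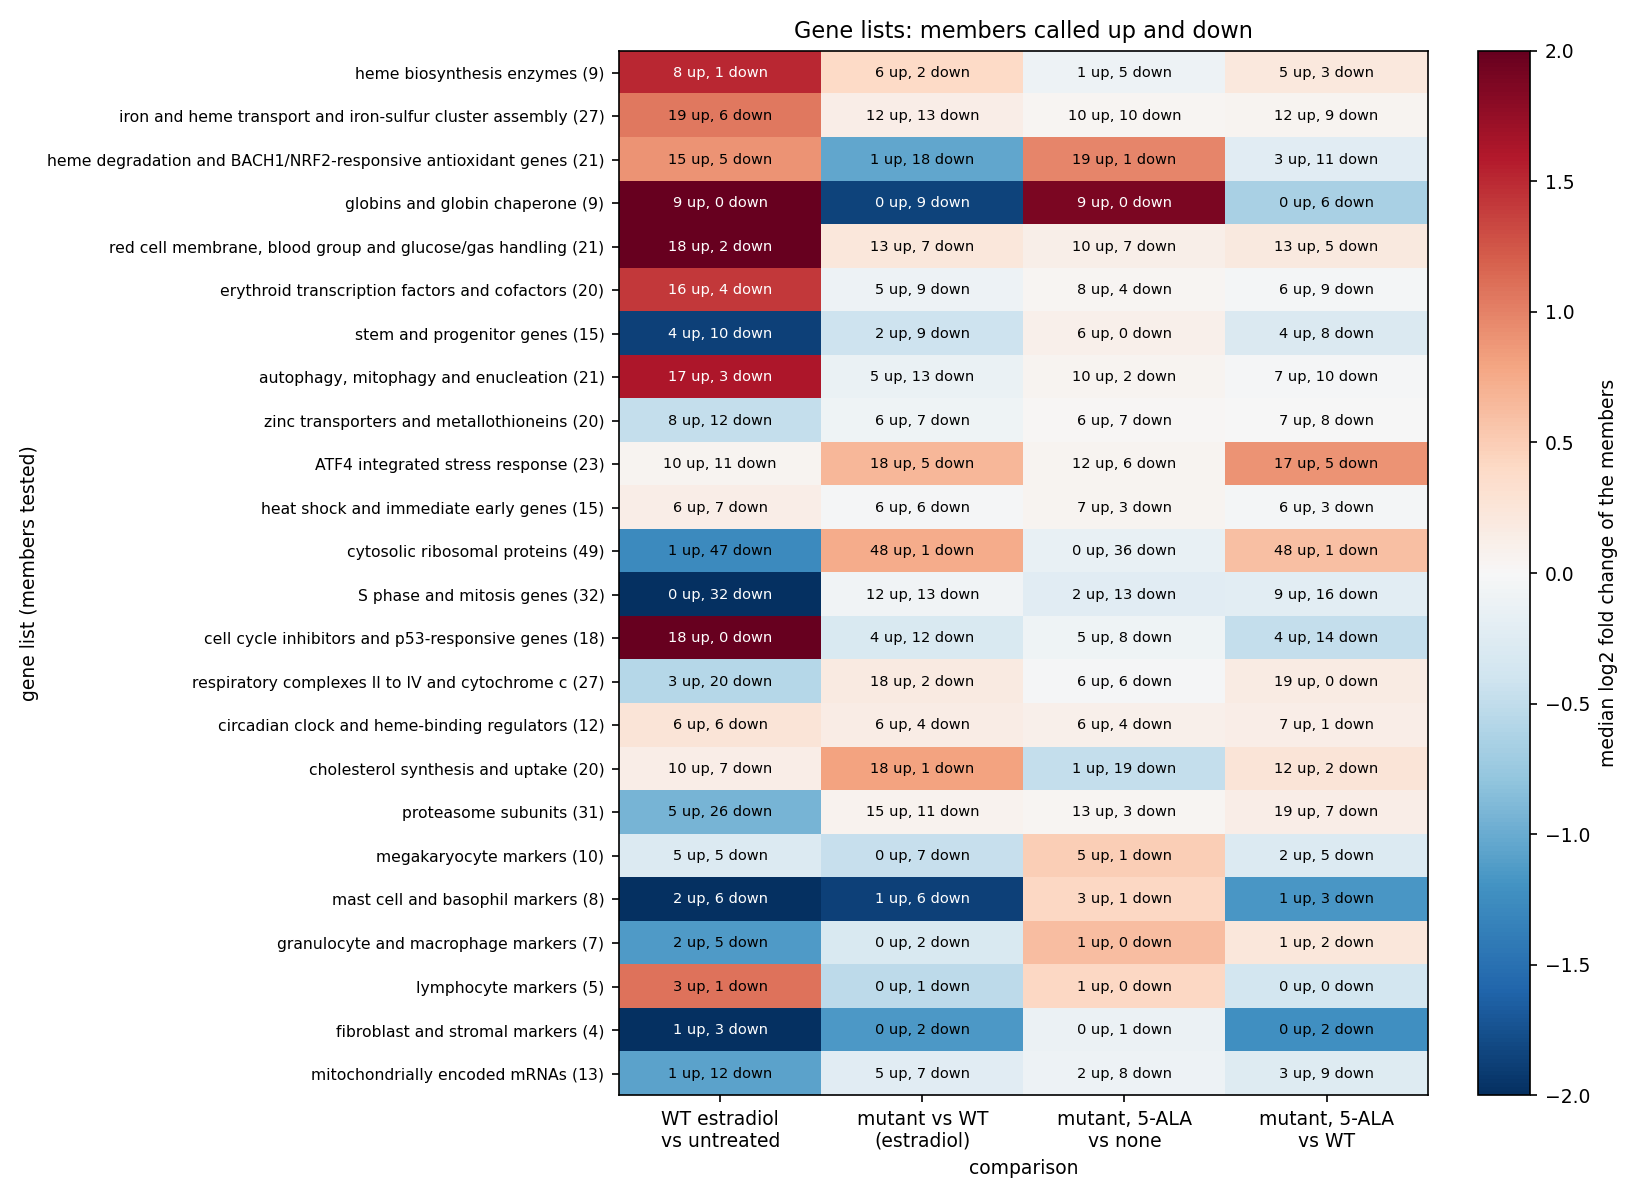
Members called higher (up) or lower (down) in each of 24 gene lists (rows, with the number tested) and 4 comparisons (columns), with the color giving the median log2 fold change of the members from -2 to 2. The globin, antioxidant, cholesterol and ribosomal medians, among others, change sign between the mutation and 5-ALA columns. The ribosomal change with 5-ALA is small (-0.156 after 0.745). In mutant cells with 5-ALA against WT cells, medians are 0.898 (ATF4), 0.602 (ribosomal), 0.258 (cholesterol), -0.222 (antioxidant) and -0.641 (globin).

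The second comparison, mutant against WT cells with estradiol in both, asks what differs in maturing cells with Alas2 expression lost. No untreated mutant cells are among the libraries. A difference already present before estradiol thus cannot be told apart from an effect of Alas2 loss during maturation. The labels also do not say how many lines the mutant libraries come from. The spread between libraries of a group therefore need not include differences between lines. Called differences, here and in the later comparison of mutant with WT cells, may thus include some that do not come from Alas2. Alas2 itself was 572.7-fold lower in mutant cells (log2 -9.16, SE 0.135, adjusted p = 8.93e-12). All 9 globin genes were lower, with Hbb-bs at 13014 ± 244 CPM against 46811 ± 381 CPM, and heme-responsive antioxidant genes fell with them. Cholesterol synthesis genes were higher, as were most ribosomal protein and ATF4 stress response genes, although these 2 lists were not called with an estimated correlation (adjusted p = 0.104 and 0.081). Of 12115 genes, 4258 were higher and 4076 lower, 627 and 799 of them by 2-fold or more, with a median absolute log2 fold change of 0.451 among the called genes. The differences were thus mostly smaller than those with estradiol, where that median was 1.35.

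After Alas2, the largest falls were those of Hbb-bh1, Trap1a, Hbb-y, Hba-x and Igsf3. Trap1a, which encodes the tumor rejection antigen P1A, went from 189.9 ± 4.9 to 1.48 ± 0.362 CPM, and Igsf3, an immunoglobulin superfamily gene, from 24.1 ± 1.79 to 0.489 ± 0.0409 CPM. The embryonic globins Hbb-bh1 and Hbb-y had log2 fold changes of -7.58 and -7.01. The largest rise was that of Ttc12, a gene of ciliary dynein assembly, from 0.0735 ± 0.0668 to 19.96 ± 0.494 CPM. It had 6 counts over the WT libraries, for a ratio of 272 with a 95% interval of 125 to 742. The sulfotransferase gene Chst10 followed, from 2.11 ± 0.321 to 36.4 ± 2.59 CPM. Next came the cytokine receptor gene Il9r (log2 3.38), the stress-induced gene Nupr1 (3.26), the translocator protein gene Tspo2 (3.26) and Pck2 (2.91).

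The globin list was lower by camera (adjusted p = 5.17e-51) and remained called with an estimated correlation (adjusted p = 0.000132). Of the 21 heme degradation and BACH1/NRF2-responsive genes 18 were lower and only Blvra, which encodes biliverdin reductase A, was higher (adjusted p = 2.81e-33, and 0.00121 with an estimated correlation). Hmox1 was at 26.4 ± 0.370 CPM against 276 ± 3.08, the sulfiredoxin gene Srxn1 at 17.7 ± 1.58 against 212 ± 3.08, and the cystine transporter gene Slc7a11 at 11.4 ± 0.805 against 57.3 ± 1.90. Bach1 mRNA itself had a log2 fold change of -0.09 (adjusted p = 0.000781). Cholesterol synthesis and uptake genes were higher in 18 of 20 cases (adjusted p = 2.5e-13, and 0.0164 with an estimated correlation). They included Mvk (log2 1.42), Lss (1.27) and Sqle (1.13), enzymes of sterol synthesis. Megakaryocyte markers were lower in 7 of 10 cases and higher in 0 (adjusted p = 0.00024, and 0.0489 with an estimated correlation), led by the integrin gene Itgb3 (log2 -2.19).

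Ribosomal protein genes were higher in 48 of 49 cases, with a median log2 fold change of 0.745 (adjusted p = 8e-26, and adjusted p = 0.104 with an estimated correlation). They took 3.54 ± 0.0597% of counts in mutant and 1.98 ± 0.00995% in WT cells. Rpl12 and Rps18 had log2 fold changes of 1.35 and 1.03. ATF4 stress response genes were higher in 18 and lower in 5 of 23 cases (adjusted p = 6.97e-16, and adjusted p = 0.081 with an estimated correlation). Psat1, an enzyme of serine synthesis, was at 159.6 ± 1.48 CPM against 29.98 ± 0.977, and the 5 lower genes were Slc7a11, Eif2ak1, Sesn2, Ppp1r15a and Cebpb. Cell cycle inhibitors and p53-responsive genes were lower in 12 and higher in 4 of 18 cases (adjusted p = 0.00253, and adjusted p = 0.104 with an estimated correlation), with Btg2 at -1.03. The 4 higher genes were Cdkn2c, a kinase inhibitor (1.58), Gadd45a, Sesn1 and Cdkn1b. Stem and progenitor genes were lower in 9 and higher in 2 of 15 cases (adjusted p = 0.0174, and adjusted p = 0.218 with an estimated correlation), with Kit at -2.30, Myb at -2.15, Gata2 at -1.09, and Ikzf1 and Etv6 higher. Respiratory complex genes were higher in 18 of 27 cases and lower in 2, Sdhc and Cox15 (adjusted p = 0.0448). That call was lost with DESeq2 size factors (adjusted p = 0.0541), a stricter filter (adjusted p = 0.0679) and an estimated correlation (adjusted p = 0.561).

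Heme synthesis enzymes other than Alas2 were mostly higher, with 6 of 9 higher and 2 lower, Alas2 and Fech (adjusted p = 0.127). The list's median was 0.406 and its mean -0.618, the latter through Alas2. Alad, which uses 5-ALA, was at 563 ± 10.9 CPM against 260 ± 2.46, and Alas1 had a log2 fold change of 0.83. Iron and heme transport genes split, 12 higher and 13 lower of 27 (adjusted p = 0.639). Steap3, an iron reductase, had 1.86 and Aco1, an iron regulatory protein, 1.31. Slc48a1 and Flvcr1, both genes of heme transporters, had -1.40 and -1.11. The metallothionein genes Mt2 and Mt1 were higher (2.51 and 2.05) and Slc30a1 lower (-1.77) in a zinc list with 6 higher and 7 lower of 20 (adjusted p = 0.49). Red cell membrane genes were higher in 13 and lower in 7 of 21 cases (0.861), erythroid transcription factors in 5 and 9 of 20 (0.49), and autophagy genes in 5 and 13 of 21 (0.376). The lists for S phase and mitosis (12 and 13 of 32), proteasome (15 and 11 of 31), heat shock (6 and 6 of 15), circadian regulators (6 and 4 of 12) and mitochondrial mRNAs (5 and 7 of 13) had adjusted p values from 0.861 to 0.877. Mast cell genes were higher in 1 and lower in 6 of 8 cases (0.49), granulocyte genes lower in 2 of 7 (0.49), lymphocyte genes in 1 of 5 (0.861) and stromal genes in 2 of 4 (0.759). Adjusted over the list alone, the counts changed only for iron (13 higher), proteasome (16 higher) and lymphocyte genes (0 lower). The median, mean and test also differed in sign for the iron, zinc, S phase, heat shock, proteasome and erythroid transcription factor lists.

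Genes changed by estradiol in WT cells overlapped with those changed in mutant cells. Of the 5243 genes higher with estradiol, 2584 were lower in mutant cells (1764 by independence) and 1254 higher (1843). Of the 5621 lower with estradiol, 2708 were higher in mutant cells (1976) and 1243 lower (1891). In limma-trend on log2(TPM + 1) 1484 were higher with estradiol and lower in mutant cells, and 701 lower in both. Both comparisons use the WT estradiol libraries, so part of the excess may come from shared controls. The covariance of the fold changes across genes was -0.4577, against -0.05167 in 20 simulations of unchanged groups with the same shared libraries. The simulations gave a mean of 0.05 genes called in each of the 2 opposite patterns, against 2584 and 2708 here. The simulated groups had equal means, so almost no gene could be called in them. These counts therefore cannot say how much of the excess comes from the shared libraries. Across all genes r was -0.2536 against -0.5065, and 62.96% had opposite signs against 66.64%, so these 2 measures did not exceed the simulations. In unchanged groups both come from the shared libraries alone, so they do not size the shared part either. Hmox1, Slc4a1 and Btg2 were among the genes higher with estradiol and lower in mutant cells, and Rpl12, Psat1 and Pck2 among those with the opposite pattern.

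Neighbouring genes on chromosomes 16 and 3 shifted together in mutant cells. On chromosome 16 (3744093 to 5255983) all 31 tested genes with at least 1 CPM, from Zfp263 to Eef2kmt, were higher, 29 of them past the test, with a median log2 fold change of 1.17. With 5-ALA the segment's median against mutant cells without it was -0.0966. On chromosome 3 (94443318 to 95760206) 29 of 33 genes from Mrpl9 to Tars2 were lower, with a median of -0.619. On chromosome 17 the 7 windows of 25 genes centred from Gm20683 to Pigq had a median of 0.582, just above the 95% point of the highest windows in shuffled order (0.571). Without the genes of both segments, 4226 genes were higher and 4048 lower.

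**Figure D4:**
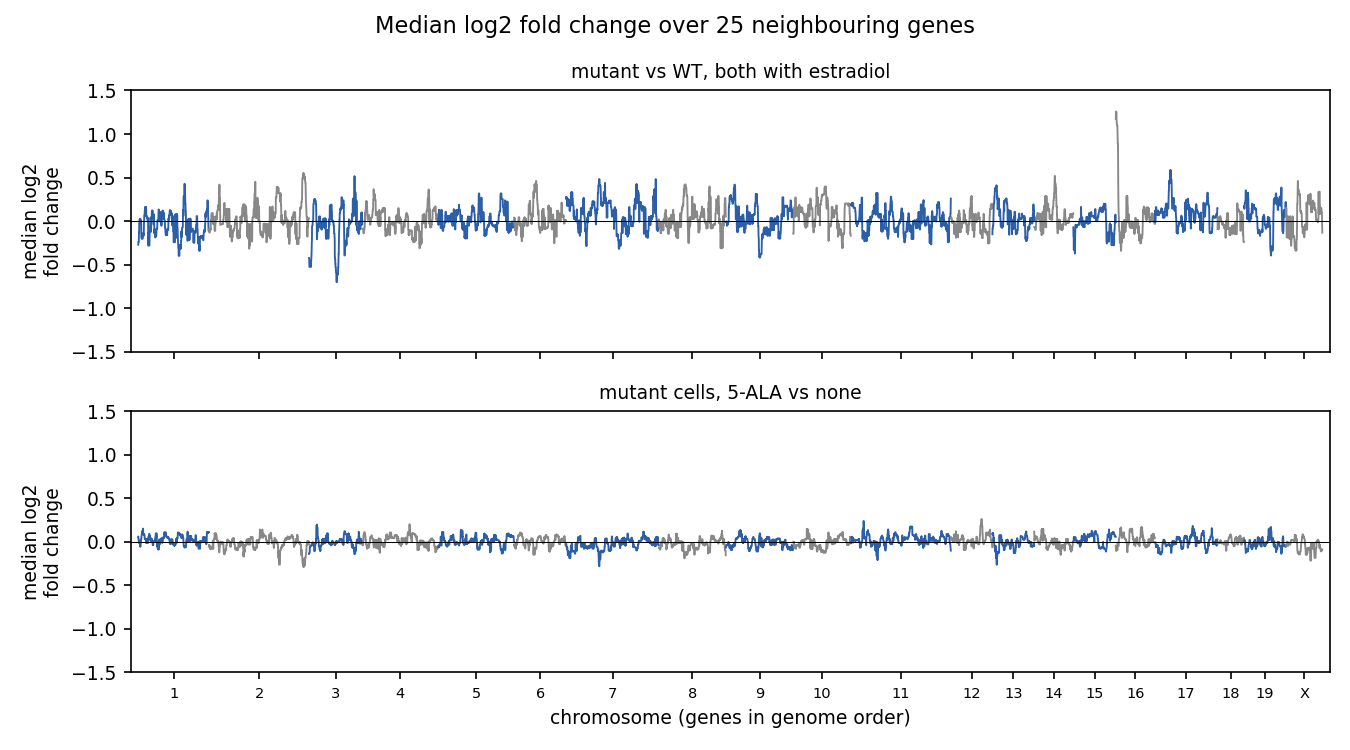
Median log2 fold change over 25 neighbouring genes along the genome (genes in order, chromosomes in alternating colors), for mutant against WT cells with estradiol (top) and for mutant cells with 5-ALA against those without (bottom). The largest medians are 1.26 on chromosome 16 and -0.703 on chromosome 3 in the top plot.

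The counts of the mutant comparison differ in limma-trend on log2(TPM + 1), which changes unit, scaling and test together. There the median over all genes shifted to 0.125, and 70.7% of the calls were higher in mutant cells against 51.1% here. In it 2326 genes were lower, 222 of them by 2-fold or more. TPM were not scaled further between libraries. In the alternatives on counts, single libraries left out aside, the share ran from 48.8% (DESeq2 size factors) to 53.5% (3 libraries left out together).

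The third comparison, mutant cells with estradiol and 5-ALA against mutant cells with estradiol alone, asks what changes when the missing heme precursor is supplied. No WT cells with 5-ALA are among the libraries. A change that 5-ALA makes in any of these cells thus cannot be told apart from the return of a mutant deficit. Globin and antioxidant genes rose and cholesterol synthesis genes fell. Hbb-bs went from 13014 ± 244 to 47823 ± 1120 CPM and Hmox1 from 26.4 ± 0.370 to 150 ± 6.65 CPM (log2 2.51, SE 0.0341, adjusted p = 8.21e-30). Alas2 stayed low, at 7.64 ± 2.20 and 12.3 ± 0.237 CPM (log2 0.72, adjusted p = 0.00885). On log2(TPM + 1) its change missed the threshold (0.41, adjusted p = 0.0725). Of 12115 genes, 2620 were higher and 2543 lower in the edgeR test, but only 215 and 65 by 2-fold or more.

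The 6 largest rises were those of Hbb-bh1 (log2 5.15), Hbb-y (from 5.02 ± 0.407 to 150.5 ± 4.53 CPM), Hbb-bt (log2 2.60), Hmox1 (2.51), Srxn1 (2.27) and the tubulin gene Tubb2a (2.12). The largest falls were those of the metallothionein genes Mt2 (-1.23) and Mt1 (from 677 ± 23.8 to 316 ± 26.8 CPM), then Fam162a (-1.19), Zfhx4 (-1.09), Pdia2 (-1.06) and Hmgcs1 (-0.97). Hmgcs1 encodes the HMG-CoA synthase that starts sterol synthesis, and it went from 675 ± 15.5 to 343 ± 4.33 CPM, against 344 ± 2.09 CPM in WT cells with estradiol. Gata1 and Gata2 had log2 fold changes of -0.02 and -0.02 and did not pass the test (adjusted p = 0.657 and 0.748). On log2(TPM + 1) both passed it, with -0.21 and -0.20 beside a shift of -0.152 in the median of all genes.

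All 9 globin genes rose (camera adjusted p = 2.28e-92, and 1.5e-05 with an estimated correlation). Of the 21 heme degradation and BACH1/NRF2-responsive genes 19 rose and Blvra fell (adjusted p = 8.57e-88, and 3.18e-05 with an estimated correlation). Slc7a11 had a log2 fold change of 2.05, and Nqo1, a quinone reductase gene, of 1.31. Cholesterol genes fell in 19 of 20 cases (adjusted p = 1.82e-32, and 0.000261 with an estimated correlation). Lss had a log2 fold change of -0.81. Megakaryocyte markers rose in 5 (Plek, Pf4, Itgb3, Gp5 and Itga2b) and fell in 1 (Gp1ba) of 10 cases (adjusted p = 2.86e-09, and 0.00247 with an estimated correlation), led by Plek (1.78), a platelet kinase substrate, and the platelet factor gene Pf4 (1.54). The iron and heme transport list was called higher (adjusted p = 4.44e-05, and 0.0465 with an estimated correlation) although 10 of its 27 genes rose and 10 fell. Its largest changes were rises of the iron exporter gene Slc40a1 (1.24), the heme transporter genes Slc48a1 (1.18) and Flvcr1 (1.02), and the transferrin receptor gene Tfrc (0.76). The median of the iron list was 0.0341. Slc40a1, Slc48a1, Fth1 and Ftl1 also belong to the antioxidant list, so this call is not separate from the rise of that list.

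Further lists were called by camera with the preset correlation alone. Ribosomal protein genes fell in 36 of 49 cases and rose in 0 (median -0.156, adjusted p = 3.23e-06, and adjusted p = 0.409 with an estimated correlation). Heme synthesis enzymes fell in 5 of 9 cases and Alas2 rose (adjusted p = 0.0255, and adjusted p = 0.148 with an estimated correlation). Alas1 fell to 4.21 ± 0.0596 from 8.28 ± 0.280 CPM, and Alad had -0.47. S phase and mitosis genes fell in 13 of 32 cases and rose in 2, Mcm4 and Mcm7 (adjusted p = 0.0051, and adjusted p = 0.26 with an estimated correlation). In each pair of values that follows, the second is the adjusted p with an estimated correlation. Red cell membrane genes rose in 10 and fell in 7 of 21 (0.0154, and 0.148). Proteasome subunits rose in 13 of 31 and fell in 3, Psmc6, Psmd4 and Psmd6 (0.0154, and 0.409), and ATF4 genes rose in 12 and fell in 6 of 23 (0.0262, and 0.474). Stem and progenitor genes rose in 6 of 15 (0.0196, and 0.257), among them Spi1 (1.34) and Myc (1.02). Mitochondrial mRNAs fell in 8 of 13 and rose in 2, mt-Co1 and mt-Atp6 (0.0206, and 0.511).

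No call was made for erythroid transcription factors (8 higher, 4 lower of 20, adjusted p = 0.314), autophagy (10 and 2 of 21, 0.214), zinc (6 and 7 of 20, 0.244) or heat shock genes (7 and 3 of 15, 0.215). Nor was one made for cell cycle inhibitors (5 and 8 of 18, 0.214), respiratory complexes (6 and 6 of 27, 0.622) or circadian regulators (6 and 4 of 12, 0.183). Mast cell (3 and 1 of 8, 0.53), granulocyte (1 and 0 of 7, 0.179), lymphocyte (1 and 0 of 5, 0.898) and stromal markers (0 and 1 of 4, 0.569) passed no list test either. In the zinc list Slc30a1 rose from 397 ± 6.43 to 850 ± 4.94 CPM while Mt1 and Mt2 fell, and the median and the mean differed in sign. Adjusted over the list alone, counts rose by 1 or more for iron (11 higher), erythroid factors (5 lower), autophagy (3 lower), zinc (7 higher), heat shock (4 lower), proteasome (4 lower) and mast cell genes (5 higher), and the lymphocyte count went to 0.

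Many mutant-WT differences went the other way with 5-ALA. Of the 4258 genes higher in mutant cells, 1912 fell with 5-ALA (893.8 by independence) and 366 rose (920.8). Of the 4076 lower ones, 1848 rose (881.5) and 301 fell (855.6). The near balance of 1912 and 1848 was not kept in limma-trend on log2(TPM + 1), with 4185 and 549. Both comparisons use the mutant estradiol libraries, so part of the excess may come from them. In 20 simulations of unchanged groups the covariance of the fold changes was -0.05587, against -0.1862 here, and r across genes was -0.487 against -0.47. The simulated r comes from the shared libraries alone, so it does not size their part here. Genes are not independent replicates.

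The 6 genes lower in mutant cells with the largest return were Hbb-bh1, Hbb-y, Hba-x, Hbb-bt, Hmox1 and Srxn1. The 6 in the other direction were Mt2, Mt1, Pdia2, Hmgcs1, the phosphoribosyl pyrophosphate synthetase gene Prps2, and Tspo2. Among genes changed by 2-fold or more, 5-ALA undid a median of 32.9% (quartiles 11.6 to 58.8) of the log2 difference in the 799 lower genes and 21.7% (6.77 to 36.3) in the 627 higher ones. The median was 80.6% for 16 antioxidant genes that differed by at least 0.5 on the log2 scale, 68.8% for 8 globins and 63.4% for 15 cholesterol genes. It was 19.4% for 42 ribosomal protein genes and 5.65% for 15 ATF4 genes. With genes of more than 1 list left out, it was 68.8% for 12 antioxidant and 2.4% for 14 ATF4 genes, and among 15 lists it ran from 2.4% to 70.5%, the latter for 5 proteasome genes. Low medians were not particular to ATF4 and ribosomal genes. Red cell membrane genes had 4.44%, S phase genes 10.4%, cell cycle inhibitors 10.8%, and stem and progenitor genes 15.6%. The remaining lists had 30.9% (erythroid transcription factors) or more. The share undone and the lists given first for it were not part of the fixed design.

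**Figure D5:**
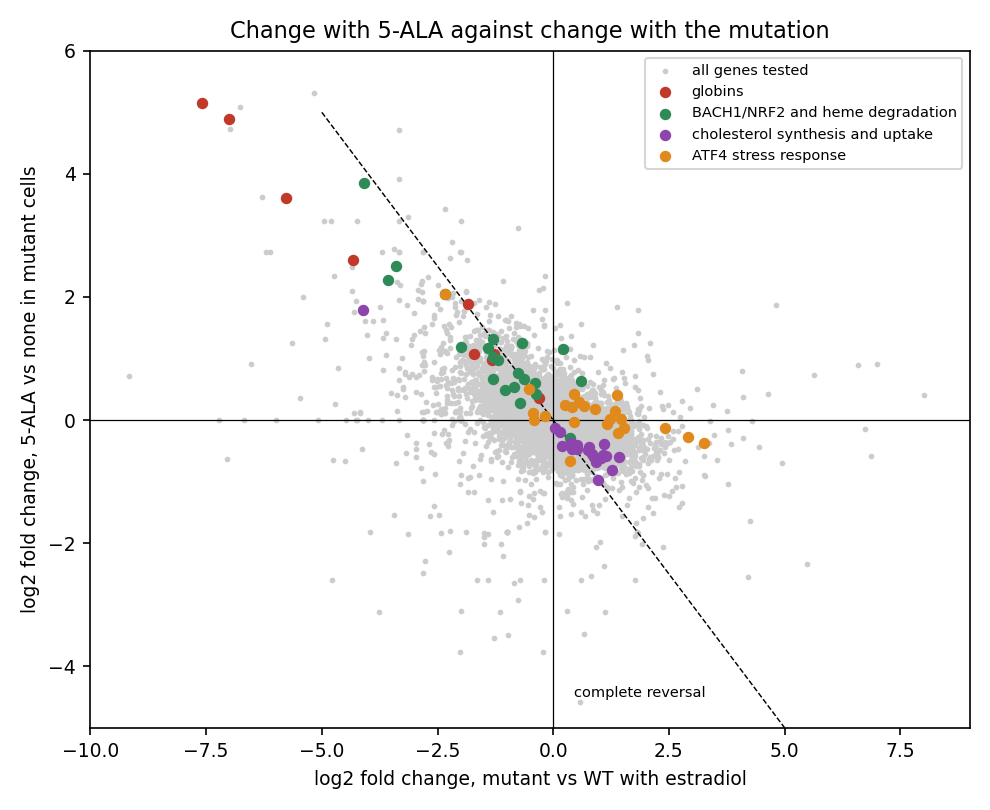
Log2 fold change with 5-ALA in mutant cells against log2 fold change between mutant and WT cells with estradiol, 1 point per gene among 12115 tested, with 4 gene lists in color and a dashed line for complete reversal. Most globin, antioxidant and cholesterol genes lie between the horizontal axis and the dashed line, and most ATF4 genes lie near the horizontal axis.

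The direction split of the third comparison differs in limma-trend on log2(TPM + 1), where 12.4% of the calls were higher, against 50.7% here. There 806 genes were higher and 5719 lower. TPM were not scaled further between libraries, and the median of all genes lay at -0.152, so the split goes with a shift of all genes. In the alternatives on counts, single libraries left out aside, the share ran from 46.2% (no filter) to 50.7% (replicate block). Fitted on its own 6 libraries, it had 43 genes lower by 2-fold or more in place of 65.

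The fourth comparison, mutant cells with estradiol and 5-ALA against WT cells with estradiol, asks what still differs once 5-ALA is supplied. Hbb-bs had 47823 ± 1120 CPM against 46811 ± 381 (log2 0.03, adjusted p = 0.771), while the adult globins Hba-a1 (log2 -0.21), Hba-a2 (-0.33) and Hbb-bt (-1.73) were lower. The embryonic globins Hbb-bh1 (-2.43), Hba-x (-2.18) and Hbb-y (-2.12) stayed lower. Hmox1 was at 150 ± 6.65 CPM against 276 ± 3.08. Most ATF4 and ribosomal protein genes were still higher than in WT cells, the latter not called as a list with an estimated correlation (adjusted p = 0.159). Of 12115 genes, 4029 were higher and 3514 lower, 435 and 506 of them by 2-fold or more.

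The largest falls were those of Alas2 (log2 -8.45), Trap1a (-7.68), Igsf3 (-4.39), the phosphodiesterase gene Pde6a (-3.81), the Polycomb-related gene Sfmbt2 (-3.15) and Mid1 (-2.56). Mid1, a ubiquitin ligase gene, had 530 ± 55.7 CPM with 5-ALA and 527 ± 42.1 without, against 3134 ± 188 CPM in WT cells. The largest rises were those of Ttc12, Chst10 (4.47), Il9r (3.37), Rhag (2.91), Nupr1 (2.89) and Tspo2 (2.37). Ttc12 had a ratio of 360.3 with a 95% interval of 165 to 983. Rhag, a gene of the Rh blood group complex, had 34.8 ± 1.43 CPM against 4.61 ± 0.289 CPM in WT cells. Of the genes changed by 2-fold or more between mutant and WT cells, 570 of 627 higher ones (90.9%) were still called higher (208.5 genes by independence) and 636 of 799 lower ones (79.6%) still lower (231.8). Both comparisons use the WT estradiol libraries, so part of this may come from shared controls. In 20 simulations of unchanged groups r across genes was 0.497, against 0.8281 here, and the 2 counts averaged 0 and 0.05. In unchanged groups r comes from the shared libraries alone and almost no gene can be called, so neither measure sizes the shared part. In limma-trend on log2(TPM + 1) 195 genes were higher and 152 lower by 2-fold or more.

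ATF4 genes were higher in 17 and lower in 5 of 23 cases (adjusted p = 4.56e-31, and 0.0281 with an estimated correlation), with Pck2 at 2.65, Psat1 at 2.27 and Trib3, a stress-induced pseudokinase gene, at 1.79. The 5 lower genes were Sesn2, Ppp1r15a, Ddit4, Slc7a11 and Eif2ak1. Ribosomal protein genes were higher in 48 of 49 cases (median 0.602, adjusted p = 2.07e-24, and adjusted p = 0.159 with an estimated correlation). Globins were lower in 6 of 9 cases, and Hbb-bs, Hbq1a and Hbq1b did not pass the test (adjusted p = 5e-20, and 0.00051 with an estimated correlation). All globins together took 6.39 ± 0.207% of counts in mutant cells with 5-ALA and 2.31 ± 0.0698% without it. In WT cells with estradiol they took 6.59 ± 0.0315%. Cell cycle inhibitors and p53-responsive genes were lower in 14 and higher in 4 of 18 cases (adjusted p = 2.73e-06, and 0.0281 with an estimated correlation), with Trp53inp1 at -1.16, and with Cdkn2c, Gadd45a, Phlda3 and Sesn1 higher. Antioxidant genes were lower in 11 of 21 cases (adjusted p = 0.000851, and adjusted p = 0.152 with an estimated correlation), and Slc40a1, Prdx1 and Me1 were higher. Respiratory complex genes were higher in 19 of 27 cases and lower in 0 (adjusted p = 0.0306, and adjusted p = 0.541 with an estimated correlation), a call lost with the stricter filter (adjusted p = 0.0551).

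The remaining lists were not called. Heme synthesis enzymes were higher in 5 and lower in 3 of 9 cases (adjusted p = 0.48, median 0.21, mean -0.751), iron transport genes in 12 and 9 of 27 (0.208), red cell membrane genes in 13 and 5 of 21 (0.141) and cholesterol genes in 12 and 2 of 20 (0.091). Stem and progenitor genes were higher in 4 and lower in 8 of 15 cases (0.158), with Spi1 at 1.51 and Myb at -2.16, and mitochondrial mRNAs in 3 and 9 of 13 (0.141). S phase genes (9 and 16 of 32, 0.316), erythroid factors (6 and 9 of 20, 0.567), autophagy (7 and 10 of 21, 0.48), zinc (7 and 8 of 20, 0.585) and heat shock genes (6 and 3 of 15, 0.431) went both ways. So did circadian regulators (7 and 1 of 12, 0.365), proteasome subunits (19 and 7 of 31, 0.411) and megakaryocyte markers (2 and 5 of 10, 0.318). Mast cell (1 and 3 of 8, 0.48), granulocyte (1 and 2 of 7, 0.737), lymphocyte (0 and 0 of 5, 0.843) and stromal markers (0 and 2 of 4, 0.412) were not called. Adjusted over the list alone, the counts changed for heat shock (4 lower), respiratory (21 higher) and granulocyte genes (0 higher). The median, mean and test differed in sign for erythroid factors, autophagy, zinc, heat shock and granulocyte genes.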

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

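The tests of the chromosome segments and of the changes that 5-ALA left in place were chosen only after these patterns were seen. The matched lists for ribosomal protein genes and the other splits of the libraries were chosen earlier.

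The length column of the deposited tables is used by no comparison above. Among genes with at least 10 CPM in both groups, the abundance-weighted transcript length differed by 1.5-fold or more, with no overlap between the groups, for 37 of 6495 genes between WT cells with and without estradiol. The count was 4 of 6845 between mutant and WT cells, 1 of 7103 between mutant cells with and without 5-ALA, and 1 of 6889 between mutant cells with 5-ALA and WT cells. Examples, chosen after their values were seen, are Tmbim1 (2632 ± 30.7 bases without and 9601 ± 137 with estradiol, SD, n = 3), Snd1 (2751 ± 226 in WT and 1470 ± 88.5 in mutant cells) and Slc7a11 (4052 ± 51.9 without and 6288 ± 22.2 with 5-ALA).

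The gene counts of the 4 comparisons were set against other splits of their 6 libraries. The real splits called 10864 genes with estradiol in WT cells, 8334 between mutant and WT cells, 5163 with 5-ALA and 7543 between mutant cells with 5-ALA and WT cells. In each comparison 1 of the 10 splits, the real one, called as many, and the highest count among the others was 0 in edgeR. With 10 splits the share cannot fall under 0.05.

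Neighbouring genes shifted together in mutant cells. On chromosome 16 all 31 genes from Zfp263 to Eef2kmt were higher than in WT cells (median log2 1.17, quartiles 0.898 to 1.5), the next 31 genes had a median of -0.247, and no shuffle of the gene order gave a 25-gene window as high (highest 0.683 of 1000). With the trend of the mutant-WT change on the WT response to estradiol taken out, the largest 25-gene median on chromosome 16 was 1.19, against 0.671 for the highest in 1000 shuffles, which argues against that response as the whole cause there (chromosome 3 had -0.631, a size reached in 3 shuffles). A gain of this segment in the mutant cells stays open, since its borders were drawn around genes that were all higher and RNA cannot separate extra copies from a change of regulation. On chromosome 3 the median was -0.619 and 29 of 33 genes were lower, short of a bound of 90% for a loss, but borders and bound were set after the values were seen, so this test is void and a loss stays open.

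Ribosomal protein genes were higher in mutant than in WT cells, with a median log2 fold change of 0.745. Of 10000 lists matched on transcript length and expression, 100% had a lower median (0.206 over the lists, central 95% from 0.0226 to 0.458). Median log2 length was 9.56 in the list and 9.67 in the matched genes, which argues against length bias as the whole cause. How closely expression was matched was not measured, so a bias by expression level is not decided. Of 10000 lists matched on the WT response to estradiol and on expression, 100% had a lower median too (0.224, 0.0578 to 0.426), which argues against a smaller estradiol response shared by genes of like response. The list's call does not pass with an estimated correlation (adjusted p = 0.104). A biological cause was not tested.

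Of 1426 genes that differed by 2-fold or more between mutant and WT cells, 557 were moved back by under 20% with 5-ALA, among them Trap1a, Ttc12, Mid1 and Psat1. The segments of chromosomes 16 and 3 hold 18 of them, a count that decides nothing, since 64 tested genes could never make up most of 557. The part undone differed between lists: over 176 genes in 15 lists, 47.9% of its rank variance lay between lists, against at most 24.4% in 10000 permutations (genes taken as independent), which argues against a like part undone in every gene. A difference between the cells that does not come from Alas2 may account for some of the 557 genes and cannot be told apart from an effect of Alas2 loss that 5-ALA does not reach, since the labels do not say whether the mutant libraries come from more than 1 line.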

How the results depend on the processing

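The alternative that leaves out 3 libraries together, those with the highest share of counts at Gm42418 and Lars2, was chosen only after the data were seen, and the other tests here were chosen earlier. All 22 counts stayed within 1.5 times their value with DESeq2 size factors, globin genes left out, no filter, the stricter filter, the DESeq2 Wald test, the replicate block, those 3 libraries left out, and each library left out in turn. With 1 library left out, the range was 4079 to 4382 genes higher and 3764 to 3910 lower between mutant and WT cells, and 2152 to 2479 higher and 2176 to 2552 lower with 5-ALA. Under limma-trend on log2(TPM + 1) 13 counts moved further. They were 1818 genes higher by 2-fold or more with estradiol, and 2326 genes lower and 222 lower by 2-fold or more in mutant against WT cells. With 5-ALA they were 806 higher and 5719 lower, 37 and 23 by 2-fold or more, and against WT cells 195 higher and 152 lower by 2-fold or more. For the overlaps they were 4185 genes higher in mutant cells and lower with 5-ALA, 549 with the opposite pattern, 1484 higher with estradiol and lower in mutant cells, and 701 lower in both. That alternative changes unit, scaling, pseudocount and test together, and its TPM were not scaled further between libraries. Fitted on its own groups, the 5-ALA comparison had 43 genes lower by 2-fold or more, and the cause was not tested. Turned in sign on log2(TPM + 1) with 5-ALA were Ulk1 (-0.006187), Atg7 (-0.06578), Cox15 (-0.01015) and Srgn (-0.0877), beside a shift of -0.152 in all genes, and the lymphocyte list with estradiol turned under fry (adjusted p = 0.000303). Under fry, which does not compare a list with other genes, 47 of the 96 list results gained a call. Of the named gene values, 2215 kept their side of the threshold with 1 library left out and 23 lost it, in Uqcrq, Ms4a1, Fn1, Per2, Cd68, Nr1d1, Atg7, Ypel4 and Dbp. Without replicate 1 of WT cells with estradiol, the lymphocyte count between mutant and WT cells loses Ms4a1 (adjusted p = 0.22) and the stromal count loses Fn1 (0.054). With an estimated correlation 29 of the 96 list results lost their call. Replicate numbers do not pair the libraries (18 pairs of the same number, r from -0.104 to 0.0669). With them as a block, the stem and progenitor list with estradiol passed (0.0461), as did the cholesterol (0.0406) and mitochondrial lists (0.0409) between mutant cells with 5-ALA and WT cells. The iron, red cell membrane and ATF4 lists with 5-ALA did not (0.0966 each). On simulated data at these depths 73.1% of the smallest changes entered were found, and depth was not varied.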

Other observations

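The observations here were chosen only after the values were seen, and no test of an explanation is attached to them.

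Vim and Cpa3 fell with estradiol and were lower still in mutant cells. Vim, which encodes the filament protein vimentin, had 128.4 ± 6.44, 1.97 ± 0.169, 0.352 ± 0.250 and 0.0997 ± 0.0607 CPM in untreated WT cells, WT cells with estradiol, mutant cells with estradiol and mutant cells with 5-ALA (SD, n = 3). Cpa3, a mast cell carboxypeptidase gene, had 139.4 ± 8.23, 1.28 ± 0.106, 0.282 ± 0.176 and 0.0583 ± 0.0432 CPM.

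Some regulators of progenitor cells were lower in mutant than in WT cells with estradiol, beyond their fall with estradiol. Kit had 534 ± 3.50, 17.7 ± 0.539, 3.68 ± 0.738 and 4.69 ± 0.532 CPM in the same order. Myb had 224.9 ± 2.40, 2.12 ± 0.320, 0.486 ± 0.167 and 0.474 ± 0.139 CPM. Gata2 went from 59.8 ± 0.730 CPM in WT cells with estradiol to 28.0 ± 0.546 CPM in mutant cells.

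The neighbours of Alas2 differed between the cells as well. Apex2, whose exons overlap those of Alas2, had 14.2 ± 0.790, 25.4 ± 0.543, 11.2 ± 0.594 and 11.5 ± 0.526 CPM in the order above, with a log2 fold change of -1.19 between mutant and WT cells and 0.04 with 5-ALA. Pfkfb1 on the other side had -0.89 and 0.10.

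Gm42418 and Lars2, whose annotated loci take up reads of ribosomal RNA in many mouse libraries, held 0.443% of counts in replicate 3 of untreated WT cells, 0.85% in replicate 1 of WT cells with estradiol and 0.562% in replicate 1 of mutant cells with estradiol. The other 9 libraries had 0.18% to 0.24%.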
